A study of Homo sapiens with 3 samples.

How the data were processed

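Genomic DNA from human umbilical vessels was profiled for 5-hydroxymethylcytosine (5hmC), an oxidised form of 5-methylcytosine made by the TET enzymes. Per the labels' protocols, DNA was extracted with phenol and chloroform, and fragments that carry 5hmC were captured by selective chemical labelling (hMe-Seal). In this method a glucose with an azide group is attached to 5hmC, biotin is clicked onto it, and the tagged fragments are pulled down and sequenced. The labels gave 3 libraries, 1 each for control, gestational diabetes and preeclampsia, and the groups were taken from the clinical condition in the labels.

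The deposited files were peak lists with 1 list per library. The submitters' processing notes named CASAVA 1.4, Bowtie 0.12.9, MACS 1.4.2 and the human build hg19, without saying what each step was set to. Each deposited list gave a start and an end in base pairs and a score for every peak, which are the authors' values. The deposited score ran from 50 to 3233.06 in every list, the range that this version of the peak caller gives for 10 times the negative log10 of its p-value. The score depends on a library's depth, so it was used only to rank, filter or describe peaks within a list, and in the closing section to compare peaks matched on rank of strength. Whether the DNA of several donors was pooled, whether an input library served as background and how many reads stood behind each list were not given in the sources used here. Depth was therefore unknown, and the number of peaks and the length they covered were the only measures of how much each list held.

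Sex chromosomes and unplaced sequences were left out, so every value refers to the 22 autosomes. Chromosome lengths of hg19 came from GenomeInfoDb 1.38.1 and the cytogenetic bands of hg19, with their Giemsa stain grade, from circlize 0.4.16. The ends of 22 of the 22 autosomes were equal in both sources. The last peak on chromosome 1 ended at base 249212707, beyond the end of that chromosome in the newer human build, which fitted the stated build. The gene table supplied for names was of assembly GRCh38.p14, a different build, so no peak was assigned to a gene, an exon or a promoter. The 16 gene lists and the genomic features fixed in advance were not run, and windows of 1 Mb and cytogenetic bands took the place of genes. Transposons, which the title of the series names, were not analysed here, since no repeat annotation of hg19 was at hand.

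Overlap was the share of a library's peaks with at least 1 bp in a peak of another library, with bedtools 2.31.1 used for random placement. Each share was set beside the mean of 20 random placements of the peaks within their chromosome. Peaks of the 3 lists were also merged wherever they touched, and each merged region was classed by the libraries that had a peak in it. For bands, chromosomes and windows, peak midpoints were counted and divided by the library's number of autosomal peaks, which scaled for the size of the list. This did not remove the effect of how many low-scored peaks were called. In control the share in the darkest bands was 5.30% over all peaks, 4.69% among the 84648 top-scored peaks and 3.94% at a score of 100 or more. Ratios of these shares were given on a log2 scale. For windows 0.5 was added to both counts, and a window was compared where the pair of libraries held 10 or more peaks in it. Intervals were exact 95% binomial intervals (Clopper-Pearson), conditional on the total for a ratio. They cover counting error only and say nothing of the spread between donors. Counts of windows at least 2-fold apart were set beside 100 Poisson draws with equal shares. The draws treat the lists as independent, although most peaks are shared, so they overstate the noise between lists and could not show an excess of differing windows. The comparisons against control used the same control library, so the correlation between them was set beside the same draws against that library.

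With 1 library per condition no test across conditions was possible and no p-value was computed. The named windows were chosen by a rule fixed before the data were examined. Windows were ranked by the bound of the interval nearest to 1, and the 5 highest and 5 lowest of each comparison were named. The window ratios were tested on simulated counts drawn from the preeclampsia and control totals. Of the simulated windows with a true 2-fold difference, 43.8% came out at least 2-fold apart and 74.0% had an interval that excluded equality. Of unchanged windows, 3.28% came out at least 2-fold apart and 3.91% had an interval that excluded equality. With a true 4-fold difference, a log2 ratio of 2, 97.8% of windows were recovered. The simulated lists were drawn independently, so these rates do not carry over to lists that share most of their peaks.

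Alternatives fixed in advance were a score of 100 or more, the same number of top-scored peaks from each library (84648), the 50% of each library's peaks with the highest scores, 50% reciprocal overlap, merging across 500 bp, base pairs in place of midpoints, a minimum of 20 peaks per window and centring on the median window. Joining of peaks within 3 kb, random placement within the same 1 Mb, the tests of peak width and all work on broad domains were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.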

Results

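The 5hmC landscape of umbilical vessels, the arteries and vein that carry blood between placenta and fetus, was recorded in 1 library each for control, gestational diabetes and preeclampsia. Preeclampsia is hypertension of late pregnancy with organ damage, and gestational diabetes is raised blood glucose that first appears in pregnancy. The lists held 104977 autosomal peaks in control, 84648 in gestational diabetes and 100995 in preeclampsia. They covered 242.9 Mb, 263.7 Mb and 231.8 Mb, or 8.43%, 9.15% and 8.04% of the autosomes. There were no replicates, so none of the differences between libraries has a replicate check, and each compares these libraries and not the conditions.

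In all 3 libraries 5hmC peaks crowded into light cytogenetic bands and thinned out in dark ones. Light bands (stain grade gneg) are GC-rich, gene-dense and replicate early, while the darkest bands (gpos100) are AT-rich, gene-poor and replicate late. The light bands held 51.9 peaks per Mb in control, 41.5 in gestational diabetes and 48.8 in preeclampsia. Bands of the palest stained grade (gpos25) were denser still, at 57.6, 45.5 and 54.5 peaks per Mb in the same order. The darkest bands held 12.1, 9.92 and 13.1 peaks per Mb. Although the darkest bands make up 16.0% of the autosomes, they took 5.30% (95% interval 5.17 to 5.44) of control peaks, 5.40% (5.25 to 5.55) of gestational diabetes peaks and 5.97% (5.83 to 6.12) of preeclampsia peaks.

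Most 5hmC regions were common to the 3 libraries. Merging all peaks gave 111611 regions, and 62467 of them (56.0%) had a peak in every library. A further 11887 (10.7%) were found in control alone, 11140 (9.98%) in preeclampsia alone and 5771 (5.17%) in gestational diabetes alone. This order was reversed with the same number of top-scored peaks per library, where the shares were 6.03%, 7.55% and 11.1%. The pair of control and preeclampsia shared 8037 regions (7.20%), control and gestational diabetes 7554 (6.77%), and gestational diabetes and preeclampsia 4755 (4.26%). The regions of preeclampsia alone lay in the darkest bands more often than those of the other classes. Their share there was 12.5% (11.9 to 13.1), against 9.36% (8.55 to 10.2) for gestational diabetes with preeclampsia and 8.39% (7.79 to 9.01) for control with preeclampsia. The share was 7.83% (7.36 to 8.33) for control alone and 7.59% (6.92 to 8.30) for gestational diabetes alone. For control with gestational diabetes it was 5.55% (5.04 to 6.09), and for regions of all 3 libraries 5.03% (4.86 to 5.21).

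**Figure D1:**
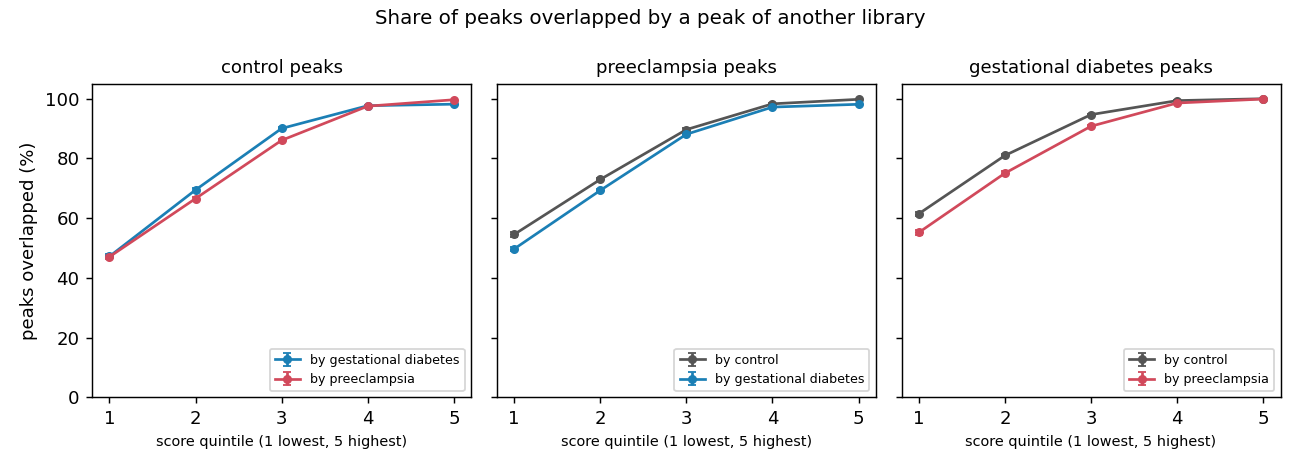
Percent of peaks of each library (1 panel per library) overlapped by a peak of another library, by score quintile within the list, from 1 (lowest) to 5 (highest). Points are shares and bars exact 95% binomial intervals, most of them smaller than the points; among control peaks the share overlapped by preeclampsia rises from 47.0% to 99.6%.

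The first comparison set preeclampsia against control. A control peak was overlapped by a preeclampsia peak in 79.3% of cases (79.1 to 79.6), and a preeclampsia peak by a control peak in 83.0% (82.8 to 83.2). Random placement within the chromosome gave 14.6% and 15.1%, and placement within the same 1 Mb gave 29.5% and 30.4%. The unshared peaks were mostly low-scored ones. In the lowest score quintile of control peaks 47.0% were overlapped, and in the highest quintile 99.6%, where 82 of 20996 peaks had no preeclampsia counterpart. Median peak widths were close, at 1676 bp in control and 1693 bp in preeclampsia.

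The darkest bands held a larger share of peaks in preeclampsia than in control, by 1.13-fold (1.09 to 1.17). The log2 ratio of shares was -0.03 (-0.05 to -0.02) in gneg, -0.03 (-0.06 to 0.01) in gpos25, 0.03 (0.00 to 0.07) in gpos50, 0.09 (0.05 to 0.13) in gpos75 and 0.17 (0.12 to 0.22) in gpos100 bands. Of 70 gpos100 bands with enough peaks, 64 had the higher share in preeclampsia, against 168 of 366 gneg bands. The excess of gpos100 over gneg bands was seen on 17 of 17 autosomes that could be compared, with log2 differences from 0.09 on chromosome 21 to 0.34 on chromosome 8. Joining peaks within 3 kb lowered the log2 ratio of gpos100 bands to 0.10.

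**Figure D2:**
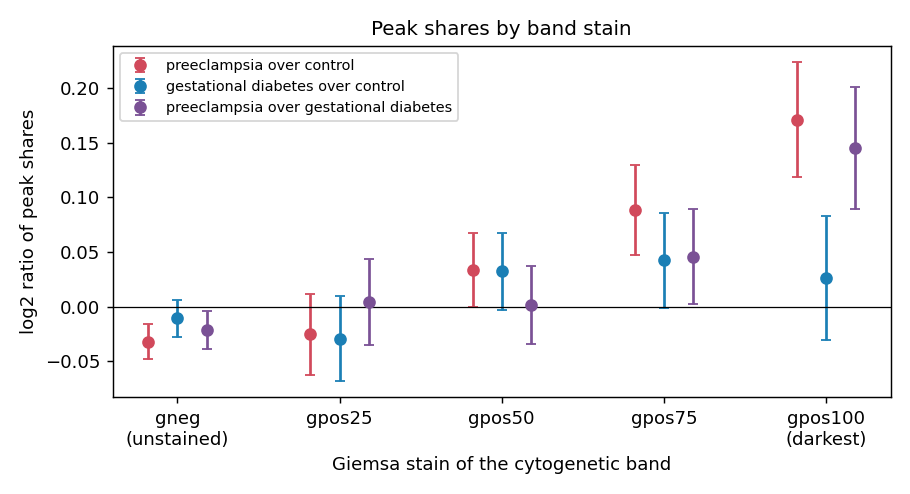
Log2 ratio of the shares of peaks in bands of each Giemsa stain grade (horizontal axis, from unstained to darkest) for the 3 comparisons of libraries. Points are ratios and bars exact 95% intervals for counting error; for gpos100 bands preeclampsia lies at 0.17 over control and gestational diabetes at 0.03.

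Single windows that stood highest in preeclampsia over control were at 2q14.1, 1q43, 3p14.1, 17q22 and 3p26.1 (hg19). The window on chromosome 2 from 116000001 to 117000000, in 2q14.1, held 20 preeclampsia peaks and 6 control peaks, a ratio of shares of 3.28 (1.34 to 10.5). In 1q43, the window on chromosome 1 from 239000001 to 240000000 held 24 against 9 peaks (2.68-fold, 1.24 to 6.78). In 3p14.1, on chromosome 3 from 68000001 to 69000000, the counts were 22 and 8 (2.75-fold, 1.23 to 7.43). In 17q22, on chromosome 17 from 54000001 to 55000000, they were 48 and 25 (1.98-fold, 1.21 to 3.38), and in 3p26.1, on chromosome 3 from 7000001 to 8000000, they were 18 and 6 (2.96-fold, 1.19 to 9.60).

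The lowest-ranked windows in preeclampsia over control were in 8q24.3 and 10p13. The window on chromosome 8 from 143000001 to 144000000 held 70 preeclampsia and 103 control peaks (0.708-fold, 0.514 to 0.966), and that on chromosome 10 from 12000001 to 13000000 held 82 and 116 (0.736-fold, 0.547 to 0.983). The next windows by rank, in 20p13 (5 against 15 peaks), 5q31.3 (57 against 83) and 13q13.1 (30 against 48), had intervals that included equality. Over 2143 windows, 29 were at least 2-fold higher and 4 at least 2-fold lower in preeclampsia, against 17 and 7 at a score of 100 or more, 9 and 1 with at least 20 peaks in the pair, 18 and 4 with peaks within 3 kb joined, and 30 and 1 in base pairs. Poisson draws with equal shares gave means of 35.9 (range 21 to 50) and 38.9 (23 to 55). Independent draws overstate the noise between lists that share most of their peaks, so this comparison could not have shown an excess. Over all these windows 8 intervals lay above equality and 2 below, where independent simulated lists without change would give 84, a number too high for the same reason. The named windows here and in the next comparisons are the extremes of a ranking, with no test behind them. Among whole chromosomes, chromosome 19 had a lower share in preeclampsia at a log2 ratio of -0.08 (-0.14 to -0.01), the 1 interval of 22 that excluded equality. Independent lists without change would give 1.1, a number again too high for lists that share most of their peaks.

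The second comparison set gestational diabetes against control. The gestational diabetes library had fewer and wider peaks. It held 0.806 times as many peaks as control (0.799 to 0.814) over a covered length 1.09 times as large, and its median peak was 2269 bp wide against 1676 bp. Peaks of 10 kb or wider numbered 2388 in gestational diabetes and 1326 in control. A gestational diabetes peak spanned several control peaks in 10873 cases, and a control peak spanned several gestational diabetes peaks in 2505. Gestational diabetes peaks were overlapped by control in 87.3% of cases (87.0 to 87.5), and control peaks by gestational diabetes in 80.5% (80.2 to 80.7), where random placement within the chromosome gave 16.6% and 15.0% and placement within the same 1 Mb 32.9% and 30.7%. In the highest score quintile of control peaks, 393 of 20996 had no gestational diabetes counterpart, against 82 without a preeclampsia counterpart. In the highest quintile of gestational diabetes peaks, 8 of 16930 had no control counterpart.

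The share of peaks in the darkest bands was not distinguishable between gestational diabetes and control at these counts. The log2 ratio was 0.03 (-0.03 to 0.08) in gpos100 and -0.01 (-0.03 to 0.01) in gneg bands, and 37 of 70 gpos100 bands had the higher share in gestational diabetes. With the same number of top-scored peaks from each library the gpos100 ratio rose to 0.20, because that setting removed low-scored control peaks and no gestational diabetes peak.

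The window in 14q32.2, on chromosome 14 from 98000001 to 99000000, stood highest in gestational diabetes with 18 peaks against 5 in control (4.17-fold, 1.60 to 15.4). Windows in 16q23.1 (chromosome 16, 78000001 to 79000000; 107 against 93 peaks, 1.43-fold, 1.07 to 1.90) and 6q26 (chromosome 6, 162000001 to 163000000; 15 against 7, 2.56-fold, 1.02 to 7.70) ranked next. The windows in 1q43 (17 against 9) and 8q21.13 (90 against 83) had intervals that included equality. In 7p21.1, on chromosome 7 from 16000001 to 17000000, gestational diabetes had 10 peaks and control 29 (0.441-fold, 0.186 to 0.903). The other windows named on the low side, in 18p11.21 (66 against 111), 1q25.3 (16 against 35), 7q22.1 (124 against 184) and 10p13 (74 against 116), had intervals that included equality. Of these, 18p11.21, 7q22.1 and 10p13 turned to a ratio above 1 once peaks within 3 kb were joined. Over 2095 windows 11 were at least 2-fold higher and 5 at least 2-fold lower, and 31 and 4 with the same number of top-scored peaks per library. The balance turned to 6 higher and 9 lower with peaks within 3 kb joined, and was 11 and 8 in base pairs, 8 and 1 at a score of 100 or more, and 4 and 1 with at least 20 peaks in the pair. Intervals lay above equality in 3 windows and below in 1, where independent simulated lists would give 86.

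Domains of 5hmC of 5 kb or more were missing more often from the gestational diabetes list than from the others, while shorter ones were missing most often from preeclampsia. Domains were stretches under peaks of both other libraries, joined across gaps of up to 500 bp. Of 387 such domains of 20 kb or more in control and preeclampsia, 28 (7.24%, 4.86 to 10.3) had no gestational diabetes peak. With gaps of up to 100 bp this share was 12.9%, and with 1000 bp 2.91%. The preeclampsia list lacked 2 of 500 (0.400%, 0.0485 to 1.44), and the control list 0 of 426 (upper bound 0.862%). For domains of 10 to 20 kb the shares were 4.07% in gestational diabetes, 0.667% in preeclampsia and 0.219% in control. For domains of 5 to 10 kb they were 2.68%, 0.814% and 0.313%. For domains of 2 to 5 kb they were 3.42%, 4.82% and 2.71%, and for 1 to 2 kb 12.3%, 16.0% and 10.7%. The longest domain without a gestational diabetes peak lay in 17q25.3, on chromosome 17 from 75370799 to 75447727 (hg19). It spanned 76.9 kb and held 4 control and 4 preeclampsia peaks. The next were in 14q32.12 (chromosome 14, 93447419 to 93487659, 40.2 kb) and 16q24.1 (chromosome 16, 85590629 to 85630625). These domains were singled out after their values were seen.

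**Figure D3:**
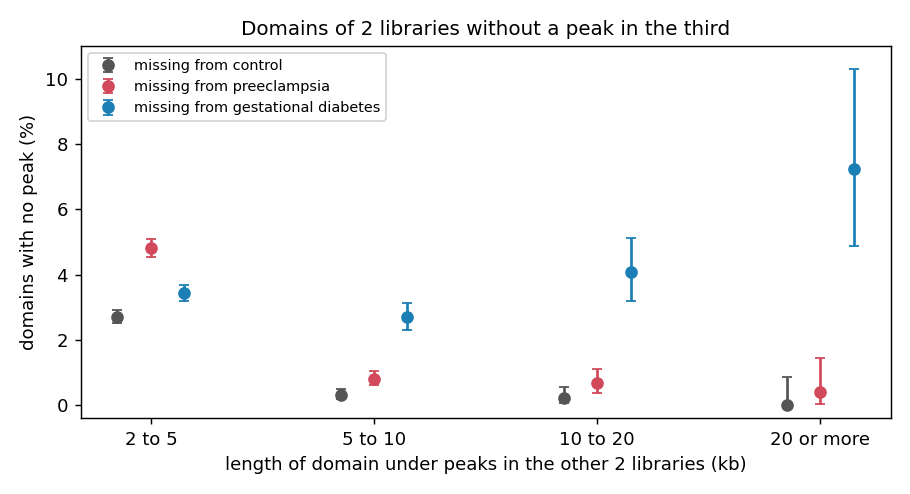
Percent of domains under peaks of 2 libraries that had no peak in the remaining library, by length of the domain in kb. Points are shares and bars exact 95% binomial intervals; for 20 kb or more, gestational diabetes lies at 7.24%, preeclampsia at 0.400% and control at 0%.

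The third comparison set the 2 disease libraries against each other. Preeclampsia again had the larger share of peaks in gpos100 bands, with a log2 ratio over gestational diabetes of 0.14 (0.09 to 0.20) and a higher share in 58 of 70 bands. With the same number of top-scored peaks per library this ratio dropped to 0.01. Preeclampsia peaks were overlapped by gestational diabetes peaks in 80.4% of cases (80.2 to 80.7), and the reverse share was 83.9% (83.6 to 84.1), where placement within the same 1 Mb gave 30.1% and 31.6%. The windows that ranked highest for preeclampsia were in 16q23.2 (chromosome 16, 81000001 to 82000000; 61 against 32 peaks, 1.59-fold, 1.03 to 2.53) and 14q31.3 (chromosome 14, 85000001 to 86000000; 24 against 9, 2.16-fold, 1.00 to 5.46). The windows in 12p13.33 (151 against 98), 7p21.1 (25 against 10) and 15q26.3 (125 against 81) had intervals that included equality, and 7p21.1 turned to a lower share in preeclampsia among peaks with a score of 100 or more.

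The windows that ranked highest for gestational diabetes over preeclampsia were in 16p13.13 (chromosome 16, 12000001 to 13000000; 62 against 48 peaks), 13q13.1 (chromosome 13, 32000001 to 33000000; 42 against 30), 14q32.2 (18 against 9) and 12q24.13 (chromosome 12, 113000001 to 114000000; 35 against 24). The ratios of preeclampsia to gestational diabetes were 0.650 (0.436 to 0.961) in 16p13.13, 0.601 (0.362 to 0.980) in 13q13.1, 0.430 (0.166 to 0.982) in 14q32.2 and 0.578 (0.327 to 0.994) in 12q24.13. The window in 20p11.23 (125 against 119) had an interval that included equality and turned the other way once peaks within 3 kb were joined. Over 2112 windows 16 were at least 2-fold higher and 2 at least 2-fold lower in preeclampsia. This balance turned to 2 higher and 11 lower with the same number of top-scored peaks per library, and was 6 and 4 at a score of 100 or more. Intervals lay above equality in 2 windows and below in 4, where independent simulated lists would give 80.

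Both disease libraries were compared with the same control library, which alone makes their ratios correlate. Across 2090 windows, which are not independent replicates, the log2 ratios of preeclampsia and of gestational diabetes over control had a Pearson correlation of 0.519 (bootstrap interval 0.474 to 0.563). Unchanged libraries drawn against the same control gave 0.484 (range 0.433 to 0.552). The covariance was 0.0396, below the 0.0841 (0.0725 to 0.103) of the draws, which overstate the noise. Windows at least 2-fold higher in both numbered 5, where the draws against the same control gave a mean of 9.69 (range 5 to 20) and independent lists of 15 and 11 windows would share 0.0789. Neither value is a sound reference for the overlap, since the draws overstate the noise and the control, as 1 library, could not be split.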

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

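Of the settings below, joining of peaks within 3 kb, random placement within 1 Mb and the joining distance of broad domains were chosen after the results were seen. Of 116 checks of the main values, 54 stayed within the counting interval or within 1.5 times a count, 61 moved further and 1 left its interval with a change of sign. Those that stayed include changes of sign around 0. With peaks within 3 kb joined, the log2 ratio of gestational diabetes over control turned to 0.0013 in gneg and -0.028 in gpos100 bands. Of the checks of named windows, 110 kept their direction and 5 did not. Counting intervals are narrow at these peak numbers, so many of the moves are small. The excess of preeclampsia over control in gpos100 bands kept its direction under all 4 settings run, at log2 ratios of 0.10 with peaks within 3 kb joined, 0.18 at a score of 100 or more, 0.21 in base pairs and 0.22 with equal numbers of top peaks. Where no cause is given below, the cause was not tested. Read depth was not given in the sources used here, so its part in any difference between lists could not be measured. No paired analysis was possible because each condition had 1 library and no test was run. Gene lists, promoter width and gene bodies with 5 kb upstream were not run, since the gene table was of another build. Keeping the 50% highest-scored peaks cannot move a ratio of peak numbers, and centring on the median cannot move a correlation. A minimum of 20 peaks and centring cannot turn a named window. None of these was counted.

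At a score of 100 or more, the ratio of peak numbers was 0.921 for preeclampsia over control, 0.820 for gestational diabetes over control and 1.12 for preeclampsia over gestational diabetes. The ratio of covered lengths was 0.922 for preeclampsia over control and 0.849 for preeclampsia over gestational diabetes. With the 50% highest-scored peaks it was 0.942 for preeclampsia and 1.07 for gestational diabetes, each over control. Overlap at a score of 100 or more was 78.5% for control by preeclampsia and 85.6% for the reverse, 81.5% for control by gestational diabetes and 87.8% for the reverse, and 82.9% for preeclampsia by gestational diabetes and 82.4% for the reverse. With the same number of top peaks these 6 shares were 81.3%, 82.1%, 88.5%, 78.9%, 86.7% and 77.0%. With 50% reciprocal overlap they dropped to 69.0%, 71.7%, 60.9%, 75.5%, 59.98% and 71.6%, and by construction this leaves out wide peaks that span several narrow ones.

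Merged regions in all 3 libraries made up 57.6% at a score of 100 or more, 56.4% with equal numbers of top peaks and 56.8% with merging across 500 bp. The share in gestational diabetes alone was 5.53%, 11.1% and 4.96% under these settings. The share in control alone was 6.03% with equal numbers and 10.5% with merging, and that in preeclampsia alone 7.93% at a score of 100 or more and 7.55% with equal numbers.

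Equal numbers of top peaks removed low-scored peaks from control and preeclampsia and none from gestational diabetes, which moved the values of the latter. The log2 ratio of gestational diabetes over control became 0.20 in gpos100 and -0.039 in gneg bands and -0.15 on chromosome 19. That of preeclampsia over gestational diabetes became 0.012 in gpos100 and 0.0018 in gneg bands, the latter a change of sign. The correlation across windows became 0.627.

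Windows at least 2-fold higher in preeclampsia than in control numbered 17 at a score of 100 or more, 9 with at least 20 peaks per window and 18 with peaks within 3 kb joined. Those lower numbered 7 at a score of 100 or more and 1 both in base pairs and with at least 20 peaks. For gestational diabetes over control, higher windows numbered 31 with equal numbers, 4 with at least 20 peaks and 6 with joining. Lower windows numbered 1 at a score of 100 or more, 8 in base pairs, 1 with at least 20 peaks and 9 with joining. For preeclampsia over gestational diabetes, higher windows numbered 6 at a score of 100 or more, 2 with equal numbers and 5 with at least 20 peaks. Lower windows numbered 4 at a score of 100 or more, 11 with equal numbers, 1 in base pairs and 1 with at least 20 peaks.

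Joining of peaks within 3 kb turned the log2 ratio of gestational diabetes over control to 0.14 in 18p11.21, 0.31 in 7q22.1 and 0.0062 in 10p13, and that of preeclampsia over gestational diabetes to 0.20 in 20p11.23. At a score of 100 or more the latter turned to -0.17 in 7p21.1. Domains of 20 kb or more without a gestational diabetes peak were 18 of 140 with joining across 100 bp and 20 of 687 with 1000 bp, against 1 of 185 and 2 of 868 for preeclampsia and 0 of 153 and 0 of 745 for control.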

Other observations

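The tests of loss of 5hmC, of weak peaks, of a few bands and of base composition were chosen after the results they bear on were seen, and the bands named next were also singled out after the fact. Among bands whose ratio of preeclampsia over control had an interval above 1, several dark ones held more peaks in preeclampsia than in both other libraries. In 4p15.1, on chromosome 4, there were 62 preeclampsia peaks, 42 control and 36 gestational diabetes peaks. In 6q16.3 the counts were 49, 31 and 23, in 8q21.3 they were 86, 58 and 49, and in 8q23.3 they were 36, 21 and 24. The log2 ratio of preeclampsia over control was 0.61 in 4p15.1, 0.71 in 6q16.3, 0.62 in 8q21.3 and 0.82 in 8q23.3. Of 722 bands compared between these libraries, 9 had an interval above 1 and 0 below. The 9 were these 4 and 2p16.3 (all gpos100), 3p24.1 and 4p15.31 (gpos75), 2q14.1 (gpos50) and 2q22.2 (gneg). Up to 36.1 unchanged bands would exclude 1 by counting alone if the lists were independent, a ceiling too high for lists that share peaks. The ratios of preeclampsia over gestational diabetes had counting intervals above 1 in 6q16.3 (1.07 to 3.07) and 8q21.3 (1.02 to 2.13), and intervals that included 1 in 4p15.1 and 8q23.3. Of 721 bands in that comparison 3 intervals lay above 1 and 1 below, the latter in 20p11.23 (0.654 to 0.995).

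In 2q14.1, a band of intermediate stain, preeclampsia held 39 peaks, control 20 and gestational diabetes 24. The light band 2q22.2 held 10, 1 and 2 peaks. At counts this low the ratio of preeclampsia to control was between 1.48 and 451. In 8p23.2, near the end of the short arm of chromosome 8, both disease libraries held more peaks than control, with 33 in preeclampsia and 31 in gestational diabetes against 22. Their intervals of the ratio to control included 1, with lower bounds of 0.882 and 0.980.

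Preeclampsia had a larger share of its peaks in the darkest bands than control. A surplus of weak peaks in the preeclampsia list was not the whole cause, since the log2 ratio among peaks with a score of 100 or more was 0.18 (0.10 to 0.26), although the score is not on the same footing in both lists. The excess was not confined to a handful of bands. Of the 70 darkest bands, 91.4% (82.3 to 96.8) had the higher share in preeclampsia. This includes bands with equal peak numbers, because the preeclampsia list is shorter, and the interval treats bands as independent. How much of the excess a few bands carried was not measured. A base composition bias of the library could give the same picture, as the ratio rose in 4 of 4 steps from one stain grade to the next darker, although the step from gneg to gpos25 lay within counting error and the median over bands fell there from -0.02 to -0.03. With 1 library per condition it cannot be told apart from a difference in 5hmC, which remains a hypothesis.

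Peaks were wider in gestational diabetes, and joining of peaks that control called separately was not the whole cause. Pairs of peaks that overlapped each other and nothing else were still 1.12 times (1.118 to 1.122) as wide in gestational diabetes as in control. A neighbour left uncalled in control could still have been joined in these pairs, which the lists cannot show. A coarser outline of every peak may account for the wider peaks. The added width was 204 bp in the highest score quintile of control peaks and 311 bp in the lowest, a ratio of 0.656. This fell just outside the range of a like widening set before the ratio was computed, and not far enough to exclude it. Ranking by control score also gave a fall in preeclampsia over control, from 73 bp in the lowest quintile to -45 bp in the highest. Those pairs together had a median difference of -1 bp. A fall of this kind thus arose without a difference in width over all pairs, so the ratio cannot decide on a like widening. In pairs ranked by gestational diabetes score, the difference of preeclampsia minus gestational diabetes fell as well. It went from -176 bp in the lowest quintile to -275 bp in the highest, a ratio of 1.56. The extra width of gestational diabetes peaks was thus larger in the highest quintile here, but smaller in the highest quintile of control scores. A biological widening of 5hmC in gestational diabetes was not tested and stays open.

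Long domains were missing from the gestational diabetes list more often than from the others, at 7.24% of those of 20 kb or more, 12.9% with joining across 100 bp and 2.91% with 1000 bp, distances chosen after the results were seen. The values speak only in part against a caller that scores wide peaks low in general, since the median score of peaks of 20 kb or more over that of peaks of 5 to 10 kb was 1.65 (1.46 to 1.94) in gestational diabetes, 1.42 (1.09 to 1.79) in control and 1.04 (0.812 to 1.34) in preeclampsia, although against peaks of 10 to 20 kb the medians were lower in preeclampsia (844 and 1205) and control (1441 and 1483), and the lists hold only regions that were called. A narrower form stays open, in which a peak joined across several neighbours scores lower than its parts. At matched strength joined peaks of 10 kb or more scored lower than single pairs in 6 of 6 ordered pairs of libraries, with median log2 differences from -0.63 to -0.22, but 4 of the 6 fell short of the 0.5 set beforehand and matching on the highest of several parts by itself lowers this difference. Because the lists hold no read coverage, loss of 5hmC from these domains and a loss of calls cannot be told apart.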
